A study of Mus musculus with 9 samples.

How the data were processed

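Hippocampus was taken from mice kept in air or exposed to chronic intermittent ethanol and treated with IgG or an antibody against IL-17A. The groups follow the sample titles, with 3 libraries in each of 3 groups, and the labels describe stranded libraries of polyadenylated RNA. The authors deposited one table of expected (estimated) counts per gene, not scaled between libraries, for 14779 genes with Ensembl identifiers. STAR 2.5.1a, RSEM 1.3.0 and the mouse build GRCm38 are named per the submitters' processing notes. The annotation release and any filter on low counts are not given in the sources used here. In the deposited table, the third-largest count of every gene is at least 6, and 27.1% of the estimated counts have decimals. A filter before deposit would remove genes of low expression, and expected counts divide reads between genes that share sequence, so values of near-identical paralogs are uncertain.

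Library totals ranged from 7372658 to 11894628 counts. The 3 libraries with label numbers 37 to 39, 1 in each group, held 10374592 to 11894628 counts, and the 6 with label numbers 54 to 60 held 7372658 to 9324263. What these numbers mean is not given in the labels, and they were used as a possible batch. No pair of libraries was identical, and the lowest chi-square per degree of freedom was 4.11 between libraries of one group and 3.99 between any 2 libraries. Symbols and coordinates were taken from GENCODE M21 on GRCm38 and matched 14628 of the identifiers. The table holds 0 genes of the Y chromosome and 0 mitochondrial genes, which were not analysed here.

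Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr by group with a minimum count of 10, which left 14696. The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling and the quasi-likelihood F-test (glmQLFit with robust=TRUE), on all 9 libraries in one fit with a mean per group and 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within a comparison, and genes under 0.05 were called. The common biological coefficient of variation was 0.189. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values were scaled with TMM, and each is given as the mean ± SD of a group. For genes with 1 to 3 counts in a group, the ratio is given with its 95% exact binomial interval of counts, and for a group at 0 counts a floor of 3 counts over the group was used. These intervals cover counting error only.

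Before the data were examined, 44 gene lists with 820 genes were fixed, of which 734 genes were in the table and 1 was matched under a newer symbol. The 41 pathway and cell type lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Adjusted p-values of lists are camera's unless fry is named, and those of genes are edgeR's. Camera with an estimated correlation and fry were run beside it. Many lists vary together between libraries of one group, which the preset correlation leaves out. A list score is the mean deviation of log2 CPM of its members from their mean over the 9 libraries.

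Genes were named by a rule fixed before the data were examined. It takes, per comparison, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (or the 10 smallest p where fewer passed), up to 4 members of each called list, list members that passed over all genes or over the list alone, genes changed back by the antibody, and a set of genes given in advance. Because the rule took 273 gene values in 3 comparisons, the text draws on a shorter set: all genes of the first and last parts, and of each list the 2 smallest p (1 for a list that was not called). All 273 gene values went through the alternatives. This shortening was set after the values were seen, and genes outside it are marked as chosen after their values were seen. The text prints examples from the shorter set, picked after the values were seen, and other genes that the rule took are not reported here.

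Alternatives fixed in advance were DESeq2 size factors, DESeq2 1.42.0, limma-voom, no filter, a strict filter (CPM above 1 in all 9 libraries), a fit of only the groups compared, robust=FALSE, the replicate number or the label number set as a block, another threshold, and each library left out in turn. Lists were also tested with a preset correlation of 0.05 and on ranks. Alternatives chosen after seeing the data were to leave out 2 libraries rich in Lars2, to leave out the genes Lars2 and AA474408, to add the thalamus and habenula, choroid plexus or striatum score as a covariate, and to use only the libraries numbered 54 to 60. The edgeR, limma and DESeq2 fits were tested on data simulated from the real means, library sizes and dispersions. The simulated genes were independent, with the same dispersion in all groups, so the recovered shares may not hold for the real libraries. For CIE+IL17 Ab against CIE+IgG, with 14696 genes, edgeR recovered 20.3% of genes changed by 1.5 times, 44.3% of those changed by 2 times and 80.3% of those changed by 4 times, with 2 false calls among 99. Overlaps and correlations of comparisons that share libraries were set against 100 simulations of unchanged groups. In a simulation of the same comparison with 5 lists shifted by 0.5 on the log2 scale and genes otherwise independent, camera recovered all 5. In the data 19 of 41 lists had an estimated correlation above 0.2, so this does not show how camera performs on them.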

Results

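Polyadenylated RNA from mouse hippocampus was sequenced in 9 libraries, 3 in each of 3 groups. Mice kept in air were given a control antibody (Air+IgG), mice exposed to chronic intermittent ethanol were given the control antibody (CIE+IgG), and ethanol-exposed mice were given an antibody against interleukin 17A (CIE+IL17 Ab). IgG is an immunoglobulin used as the control for the antibody treatment, and interleukin 17A is a cytokine of the immune system that signals through the receptor chains Il17ra and Il17rc. The series' design text gives 3 mice for each group. Estimated counts per library summed to between 7372658 and 11894628 over 14779 genes, and 14696 genes were tested. The comparisons ask which hippocampal transcripts differ after ethanol exposure, which differ with the antibody in ethanol-exposed mice, and how the antibody group compares with the air controls.

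Among the 9 libraries, the first principal component held 45.9% of the variance and the second 23.5%. The 3 CIE+IL17 Ab libraries lay at 57.1, 52.9 and 25 on the first component. The 3 Air+IgG libraries lay at -23.6, -46.2 and -22.8, and the CIE+IgG libraries at -19.4, -31.4 and 8.5. In an F-test of the 3 groups together, 839 genes differed at an adjusted p under 0.05 (edgeR quasi-likelihood). This count was 21, 191 and 23 without Air+IgG replicates 1, 2 and 3, and 152 and 390 without CIE+IgG replicates 1 and 2. It was 553, 23 and 1332 without CIE+IL17 Ab replicates 1, 2 and 3. In the 6 libraries with label numbers 54 to 60 it was 2, and without the 2 libraries rich in Lars2 (Air+IgG replicate 2 and CIE+IL17 Ab replicate 1), with 593544 and 495056 counts of this gene, it was 306.

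**Figure D1:**
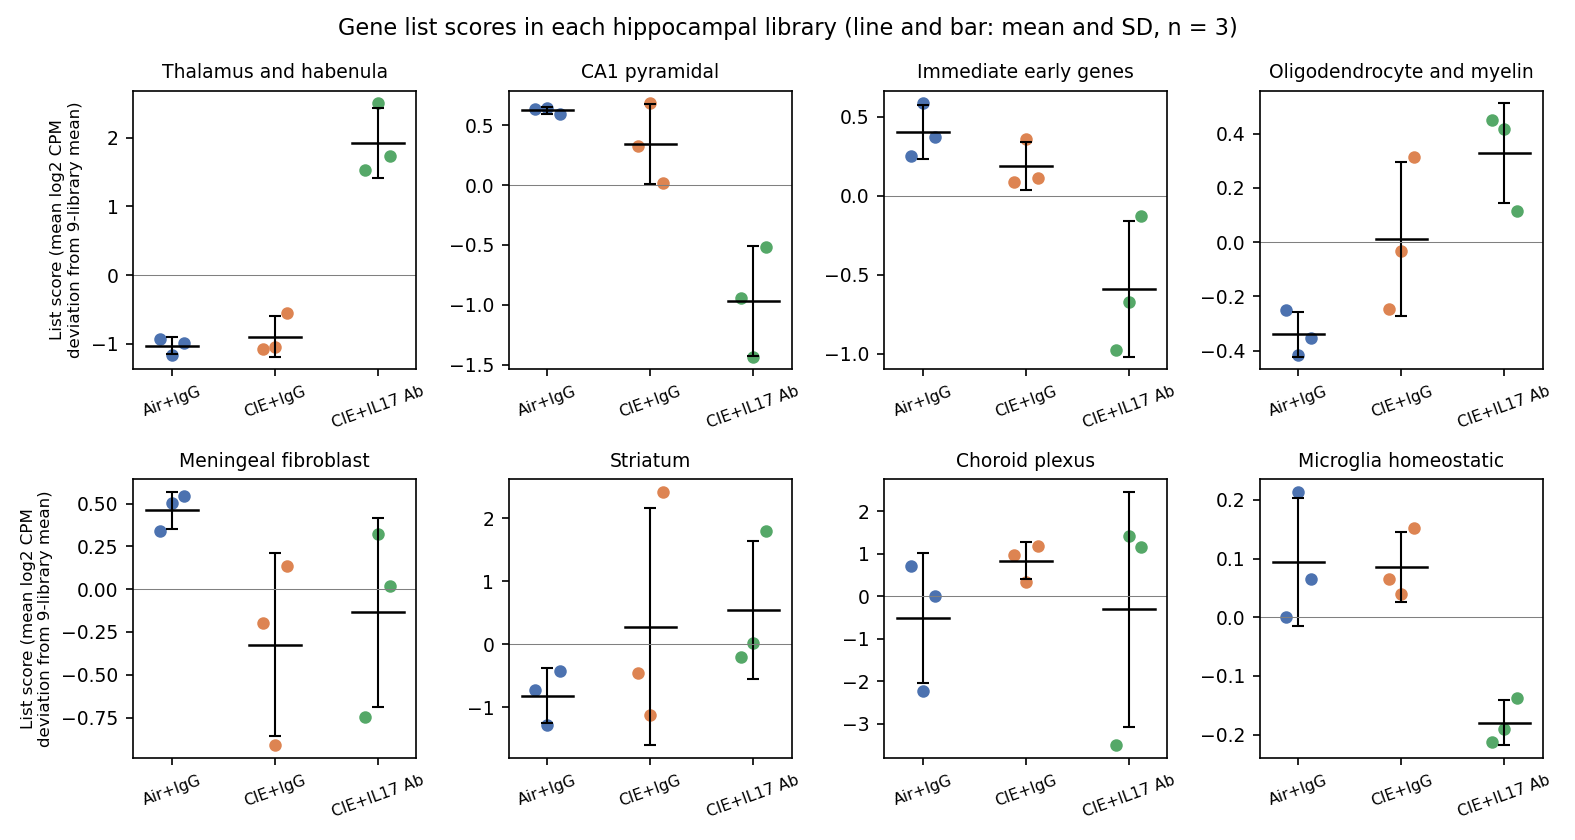
Scores of 8 fixed gene lists in each library, as the mean deviation of log2 CPM of the list members from their mean over the 9 libraries (y axis), by group (x axis). Points are libraries, the line and bar are the mean and SD of 3 libraries, and the thalamus and habenula score is above 1.5 in each CIE+IL17 Ab library and below -0.5 in each of the other 6.

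The first comparison asked which genes differ between ethanol-exposed and air-kept mice that were given the control antibody. The 10 genes with the smallest p all had lower values in CIE+IgG, and 0 of the 14696 genes passed. Slc22a6, an organic anion transporter, had 3.20 ± 0.707 CPM in CIE+IgG and 11.9 ± 3.87 CPM in Air+IgG (SD, n = 3), a log2 fold change of -1.89 with a standard error of 0.29. Ptgds, the prostaglandin D2 synthase, had 196 ± 43.3 CPM against 619 ± 241 CPM. Gjb2, a gap junction protein, had a log2 fold change of -1.53, Fmod, the extracellular matrix protein fibromodulin, had -1.60, and F13a1, coagulation factor XIII chain A, had -1.38. Fibronectin (Fn1) had -0.69, and the cystine transporter Slc7a11 had -0.88. The smallest adjusted p over all genes in edgeR's quasi-likelihood test was 0.791.

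No gene passed an adjusted p of 0.05 between CIE+IgG and Air+IgG in edgeR's test or in limma-voom, and 6 passed in DESeq2. The 6 were Ptgds, Slc22a6, Gjb2, Fn1, Fmod and Slc13a3, all lower in CIE+IgG. At an unadjusted p under 0.05, edgeR gave 406 genes, 243 higher and 163 lower, where 735 would be given by chance. On simulated counts for this comparison, with 14696 genes, the edgeR test recovered 5.9% of genes changed by 1.5 times, 68.1% of those changed by 2 times and 85.7% of those changed by 4 times. The simulated genes were independent and had the same dispersion in all groups. In the data, the 406 genes became 587 with only the 2 groups in the fit. The recovered shares may therefore not hold for these libraries. In the 6 libraries with label numbers 54 to 60 edgeR gave 0 genes, with 124 at an unadjusted p under 0.05.

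Fixed gene lists were compared as groups. Of 41 lists, 9 passed in camera with a preset correlation of 0.01, of which 6 were higher and 3 lower in CIE+IgG. No list passed with an estimated correlation, where the adjusted p of each of the 9 was 0.976, and none passed in fry. The count of lists was 14 without CIE+IgG replicate 2, and 7 in the libraries numbered 54 to 60. The meningeal fibroblast list had a median log2 fold change of -0.81, with 11 of its 14 members below 0 (adjusted p = 2.48e-09, and adjusted p = 0.976 with an estimated correlation). Of its members, 0 passed over all genes and 5 passed adjusted over the list alone, among them Slc22a6, Fmod and Aldh1a2, a retinaldehyde dehydrogenase with a log2 fold change of -1.62. The scores of this list were 0.34, 0.50 and 0.54 in the Air+IgG libraries and -0.20, -0.91 and 0.13 in the CIE+IgG libraries. Aldh1a2 also passed over the list of ethanol metabolism alone, and that list did not pass (adjusted p = 0.665), with a median of 0.02 above 0 and a mean of -0.010 below 0.

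The oligodendrocyte and myelin list had a median of 0.41, with 19 of 20 members above 0 (adjusted p = 5.65e-13, and adjusted p = 0.976 with an estimated correlation). Its members Myrf, a transcription factor of myelination, and Fa2h, a fatty acid hydroxylase of myelin lipids, had log2 fold changes of 0.48 and 0.39. No member passed over all genes or over the list alone. Its scores were -0.25, -0.032 and 0.32 in the CIE+IgG libraries and -0.25, -0.42 and -0.36 in the Air+IgG libraries, and the mean log2 fold change of 0.37 was 0.20 without CIE+IgG replicate 3. The striatum list had a median of 1.76, with all 13 members above 0, and its score was 2.42 in CIE+IgG replicate 3 and at most -0.43 in the other CIE+IgG and the Air+IgG libraries (adjusted p = 0.00122, and adjusted p = 0.976 with an estimated correlation). Without CIE+IgG replicate 3, its mean log2 fold change was -0.17 (adjusted p = 0.906), and in the libraries numbered 54 to 60 the list did not pass (adjusted p = 0.973). The choroid plexus list had a median of 1.0 and the ependymal list one of 0.93, with every member above 0 in both (adjusted p = 0.000378 and 1.18e-05, and adjusted p = 0.976 with an estimated correlation). No member of the striatum, choroid plexus and ependymal lists passed over all genes or adjusted over the list alone. The choroid plexus score was -2.24 in Air+IgG replicate 2, and without that library the choroid plexus list did not pass (adjusted p = 0.244). Its mean log2 fold change of 0.95 was 0.49 without Air+IgG replicate 2 and 1.58 without Air+IgG replicate 1. The ependymal score was -1.50 in Air+IgG replicate 2, and the mean of the ependymal list was 0.57 without CIE+IgG replicate 3 in place of 0.93. Ttr, the transthyretin of choroid plexus, had 3173 counts in Air+IgG replicate 2 and at least 22335 in the other libraries of these groups.

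The lists of fatty acid synthesis and storage and of the oxidative stress response had medians of 0.11 each (adjusted p = 0.00331 and 0.0434, and adjusted p = 0.976 with an estimated correlation). No member of either list passed over all genes. Adjusted over the list alone, 1 member of the oxidative stress list passed, Slc7a11, whose value of -0.88 is opposite to the direction of the list, and 0 of the fatty acid list. The immediate early genes, which neurons switch on after activity, had a median of -0.20, with 29 of 32 members below 0 (adjusted p = 0.00124, and adjusted p = 0.976 with an estimated correlation). Pericyte and smooth muscle genes had a median of -0.28, and Acta2, smooth muscle actin, had -0.79, and -0.26 without Air+IgG replicate 2 (adjusted p = 0.0168, and adjusted p = 0.976 with an estimated correlation). No immediate early or pericyte gene passed over all genes or adjusted over the list alone. Without Air+IgG replicate 2 the calls of these 4 lists were lost, with adjusted p of 0.115, 0.219, 0.174 and 0.324 for fatty acid, oxidative stress, immediate early and pericyte genes, and the means of -0.21 and -0.31 of immediate early and pericyte genes were -0.11 and -0.12. The oxidative stress call was also lost without Air+IgG replicate 1 (0.0835), CIE+IgG replicates 1 and 3 (0.0821 and 0.643) and CIE+IL17 Ab replicate 1 (0.0632), and the mean of 0.11 of this list was 0.036 without CIE+IgG replicate 3 and 0.18 without CIE+IgG replicate 2. The pericyte call was also lost without CIE+IgG replicate 2 (0.143) and CIE+IL17 Ab replicate 1 (0.0527). The lists of the IL-17 receptor pathway, IL-17 target genes and inflammatory cytokines did not pass, with adjusted p of 0.353, 0.972 and 0.942, and the IL-17 target list had a median of -0.061 with a mean of 0.080. Their tested members numbered 16, 11 and 22. Il17a, Il17f, Lcn2, Cxcl1, Ccl2, Il6, Tnf and Il1b are absent from the deposited table, so these lists speak only for the members tested. Il17ra had a log2 fold change of -0.22 with a standard error of 0.16, and Il17rc had 0.39 with a standard error of 0.25. Without Air+IgG replicate 1 they had -0.10 and 0.63, and Il17rc had 0.26 without Air+IgG replicate 3 and 0.22 without CIE+IgG replicate 1. Gfap, the intermediate filament of astrocytes, had 0.12, and 0.22 and 0.045 without Air+IgG replicates 2 and 3. Aif1, a microglial marker, had -0.33, and -0.22 without CIE+IgG replicate 2. None of these 4 genes passed the test.

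The second comparison asked what the antibody against interleukin 17A changed in ethanol-exposed mice. Genes of the thalamus and habenula were higher in all 3 CIE+IL17 Ab libraries than in the other 6, and 4 of 10 genes of CA1 pyramidal neurons fell against CIE+IgG over all genes. With an estimated correlation neither list passed (adjusted p = 0.217 and adjusted p = 0.657 with an estimated correlation). Chrna3, a nicotinic acetylcholine receptor subunit at chromosome 9 from 55010111 to 55026562 (GRCm38), rose from 0.970 ± 0.293 to 19.8 ± 2.58 CPM (SD, n = 3), a log2 fold change of 4.32 with a standard error of 0.33 (adjusted p = 0.00509). Pou4f1, a homeodomain transcription factor of habenular neurons, had 1 count in the 3 CIE+IgG libraries and 247 in the CIE+IL17 Ab libraries, a ratio of 240 with a 95% counting interval of 42.6 to 9510. Tcf7l2, a transcription factor of thalamic neurons, rose from 13.1 ± 12.1 to 178 ± 52.9 CPM, with 27.0 CPM in CIE+IgG replicate 3 and 5.59 and 6.56 CPM in replicates 1 and 2. In the opposite direction, Ccn3, a matricellular protein of CA1 neurons, fell from 65.8 ± 12.4 to 5.92 ± 4.34 CPM, a log2 fold change of -3.49.

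Of the genes tested, 468 passed between CIE+IL17 Ab and CIE+IgG, 261 higher and 207 lower with the antibody, and 214 of them differed by over 2 times. Among all tested genes, 25.9% had no overlap between the libraries of both groups, where chance gives 10%. None of the 468 had an overlap, which follows largely from their choice by p on the same libraries. The count depended on single libraries. It was 0 without CIE+IgG replicate 1, with 2115 genes at an unadjusted p under 0.05 in edgeR, so that no gene named here passed without that library. It was 6 without CIE+IgG replicate 2 and 726 without CIE+IgG replicate 3. It was 18, 222 and 18 without Air+IgG replicates 1, 2 and 3, and 19 and 1314 without CIE+IL17 Ab replicates 2 and 3. Within the 6 libraries with label numbers 54 to 60, 1 gene passed, which was Tcf7l2, and the 3 libraries numbered 37 to 39 held 1 library of each group. With a term for the label numbers the count was 776, with DESeq2 it was 1481, and with only the 2 groups in the fit it was 1, which was Chrna3. With the thalamus and habenula score as a term, added after seeing the data, edgeR gave 0 genes, with 1017 at an unadjusted p under 0.05, and with the striatum score it gave 178. With the thalamus and habenula score, genes named here changed sign, among them Fibcd1, Grin2d, Stard4 and Vipr2. That score has a squared correlation of 0.957 with the antibody group, so no change in this comparison can be told apart from it.

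The 10 largest rises held further receptors. Chrnb3, another nicotinic receptor subunit, had a log2 fold change of 4.91, and Gpr151, an orphan receptor of the habenula, had 3.76. The glycine receptor subunit Glra1 had 4.58 and the receptor for vasoactive intestinal peptide Vipr2 had 3.52. Among the 10 largest falls were genes with very low counts with the antibody. Ntn5, of the netrin family, had 106 counts in CIE+IgG and 2 in CIE+IL17 Ab, a ratio of 54.6 with a 95% counting interval of 14.8 to 457. Akr1c18, a hydroxysteroid dehydrogenase, had 54 counts against 2, and the keratin Krt2 had 70 against 3. Slc9a4, a sodium-proton exchanger, had -3.73 (-5.96 without CIE+IL17 Ab replicate 3), Rspo2, a Wnt signalling ligand, had -2.84, and Spink8 had -2.69.

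**Figure D2:**
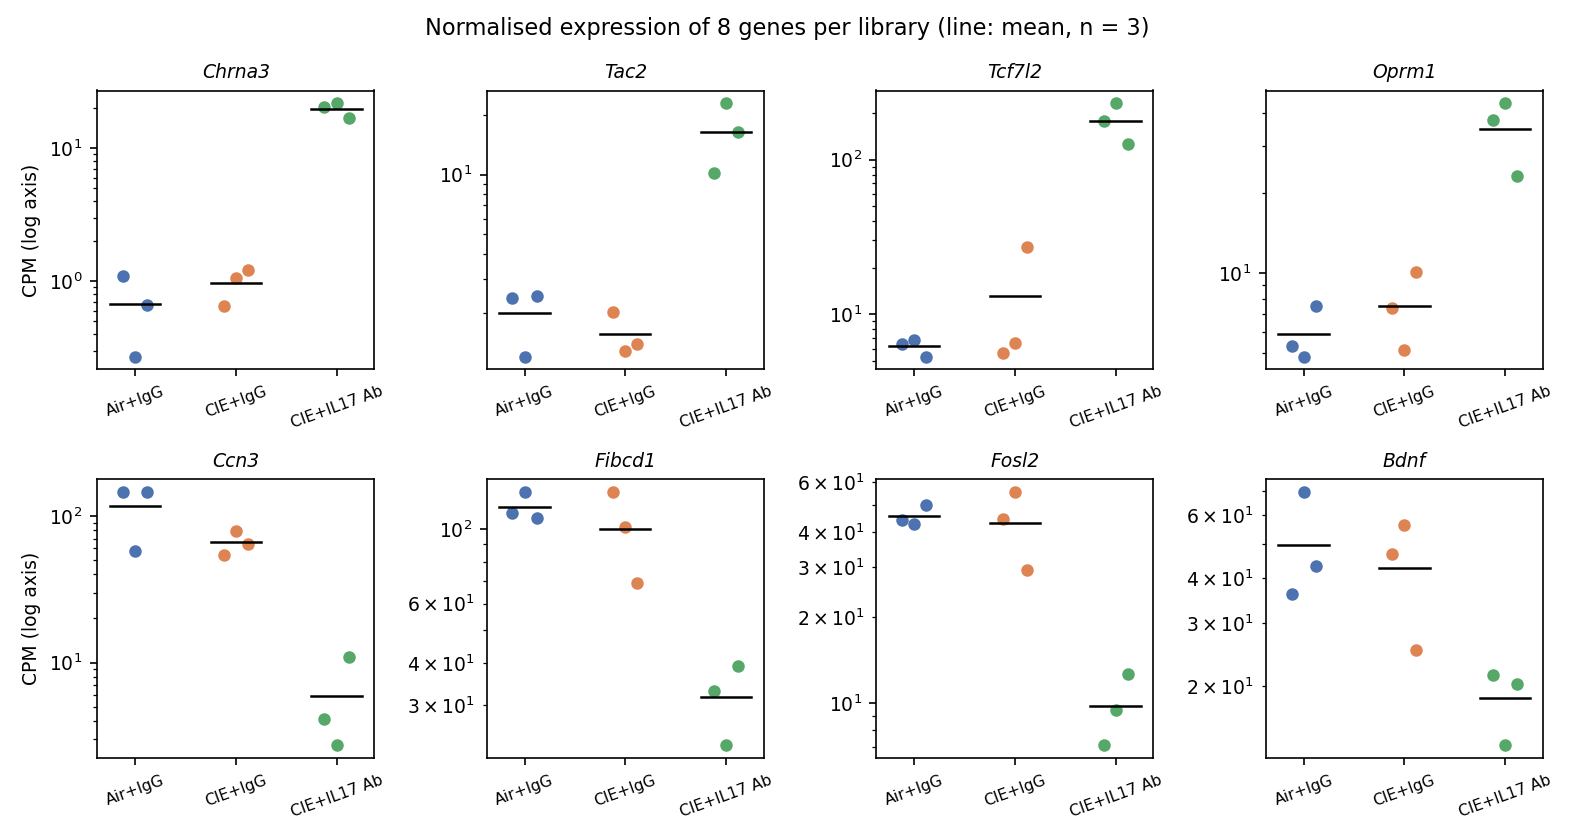
Normalised expression of 8 genes in CPM on a log axis (y axis) in each library, by group (x axis). Points are libraries and lines are means of 3 libraries, and Chrna3 has a mean of 0.672 CPM in Air+IgG, 0.970 CPM in CIE+IgG and 19.8 CPM in CIE+IL17 Ab.

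Of 41 lists, 12 passed in camera for this comparison, 6 higher and 6 lower with the antibody. None passed with an estimated correlation, and fry gave 3, the lists of thalamus and habenula, CA1 pyramidal neurons and homeostatic microglia. In the libraries numbered 54 to 60 camera gave 10 lists. The thalamus and habenula list had a median log2 fold change of 2.83, and 10 of its 11 members rose over all genes and 11 adjusted over the list alone (adjusted p = 3.76e-13, and adjusted p = 0.217 with an estimated correlation). Tac2, the precursor of neurokinin B, rose by 3.39 on the log2 scale. All 10 CA1 pyramidal genes were below 0, with a median of -1.13, and 4 fell over all genes and 5 adjusted over the list alone (adjusted p = 3.23e-05, and adjusted p = 0.657 with an estimated correlation). Fibcd1 fell from 99.6 ± 29.8 to 31.7 ± 8.28 CPM. Dentate gyrus granule cell genes had a median of -0.33, with 12 of 15 below 0 and 0 passing (adjusted p = 0.0335, and adjusted p = 0.906 with an estimated correlation). This call was lost without CIE+IL17 Ab replicate 1 (0.253) and CIE+IgG replicates 1 and 2 (0.0527 and 0.162), and the mean of -0.59 was -0.39 without CIE+IL17 Ab replicate 1, -0.38 without CIE+IgG replicate 2 and -1.03 without CIE+IL17 Ab replicate 3. The list of CA2 and CA3 pyramidal genes did not pass (adjusted p = 0.402), with a median of -0.50 and 10 of 15 members below 0. Over all genes 1 of its members rose, Cpne9 by 2.21 on the log2 scale, and 2 fell, and adjusted over the list alone 4 rose and 4 fell.

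Immediate early genes had a median of -0.87 with the antibody, with 23 of 32 below 0 (adjusted p = 6.7e-06, and adjusted p = 0.83 with an estimated correlation). Of these, 6 fell over all genes, and 16 fell and 1 rose adjusted over the list alone. Fosl2, a subunit of the AP-1 transcription factor, fell from 43.1 ± 13.1 to 9.74 ± 2.79 CPM, and Homer1, a scaffold protein of the postsynaptic density, fell from 178 ± 12.3 to 91.7 ± 25.4 CPM. The neurotrophin Bdnf had 42.8 ± 15.9 CPM in CIE+IgG and 18.5 ± 4.23 CPM with the antibody, and did not pass (adjusted p = 0.0932). It passed in DESeq2, with the label number block and without CIE+IgG replicate 3, where its log2 fold change was -1.49 in place of -1.21. The list of neuropeptide and stress systems had a median of -0.46 (adjusted p = 0.0284, and adjusted p = 0.83 with an estimated correlation). Crhbp, which binds corticotropin-releasing hormone, fell by 2.39 on the log2 scale, and Oprm1, the mu opioid receptor, rose by 2.19. Neither change can be told apart from the difference in thalamus and habenula genes. In the neuropeptide and stress list 3 genes fell and 1 rose over all genes, and 7 fell and 1 rose adjusted over the list alone, and without CIE+IgG replicate 3 the list did not pass (adjusted p = 0.211). The mean of -0.40 was -0.071 without CIE+IgG replicate 3 and -0.27 without CIE+IL17 Ab replicate 2.

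Homeostatic microglia genes had a median of -0.29, with 17 of 18 below 0, and 2 fell over all genes and 3 adjusted over the list alone (adjusted p = 9.1e-05, and adjusted p = 0.657 with an estimated correlation). Csf1r, the receptor for colony-stimulating factor 1, fell by 0.39 on the log2 scale, and P2ry12, a purine receptor, fell by 0.50. These and the other changes in this comparison cannot be told apart from the difference in thalamus and habenula genes. The astrocyte list did not pass (adjusted p = 0.116), with a median of 0.25. Its gap junction gene Gja1 rose by 0.46 on the log2 scale (adjusted p = 0.046), and passed in 1 of 9 fits with a library left out. Adjusted over the list alone, 1 astrocyte gene rose and 1 fell. The reactive astrocyte list did not pass (adjusted p = 0.901), with a median of 0.12 and a downward direction of the test, and its protease inhibitor Serpina3n fell by 1.04 on the log2 scale. All 20 myelin genes were above 0 with a median of 0.31 and 0 passing (adjusted p = 0.000196, and adjusted p = 0.83 with an estimated correlation), and the mean of 0.30 was 0.18 without CIE+IgG replicate 1 and 0.47 without CIE+IgG replicate 3. Cholesterol synthesis genes had a median of 0.19, and Stard4, a sterol transfer protein, rose by 0.90 on the log2 scale as the 1 member that passed over all genes and adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.83 with an estimated correlation). Genes of fatty acid synthesis and storage had a median of 0.19, endothelial genes 0.26, and pericyte and smooth muscle genes 0.39, with 0 passing over all genes in each, and 0, 0 and 1 adjusted over the list alone (adjusted p = 0.0269, 0.013 and 0.00213, and adjusted p = 0.83 with an estimated correlation). Without CIE+IL17 Ab replicate 2 and without CIE+IgG replicate 2, the fatty acid list (0.0732 and 0.083) and the endothelial list (0.0539 and 0.0544) did not pass, and the mean of 0.15 of the fatty acid list was 0.096 without CIE+IL17 Ab replicate 2. Ribosomal protein genes had a median of -0.11, with 32 of 38 below 0 and 0 passing (adjusted p = 0.00667, and adjusted p = 0.83 with an estimated correlation), and the list did not pass without CIE+IL17 Ab replicate 2 (0.0689).

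Grin2d, an NMDA receptor subunit, rose by 1.94 on the log2 scale, and Cacna1g, a T-type calcium channel, rose by 1.64. With the thalamus and habenula score in the fit both changed sign, and they cannot be told apart from the rise of thalamus and habenula genes. The potassium channel Kcnc2, from the inhibitory neuron list, rose by 0.82. That list did not pass in camera (adjusted p = 0.198), with a median of -0.405. In it 1 gene rose and 2 fell over all genes, and 3 rose and 6 fell adjusted over the list alone. The lists of glutamate receptor subunits, GABA-A receptor subunits and voltage-gated channels did not pass, with adjusted p of 0.5, 0.707 and 0.256. Of the glutamate receptor subunits 1 rose and 3 fell over all genes, and 4 rose and 7 fell adjusted over the list alone. Of the GABA-A receptor subunits 2 fell over all genes and 3 adjusted over the list alone, and of the channels 2 rose over all genes, and 2 rose and 4 fell adjusted over the list alone. The IL-17 receptor pathway list had an adjusted p of 0.973, and that of IL-17 target genes 0.371, with 16 and 11 tested members. In the GABA-A and IL-17 receptor pathway lists the median and mean were above 0 while the direction of the test was downward. Il17ra had a log2 fold change of -0.05 with a standard error of 0.16, and Il17rc had 0.08 with a standard error of 0.25. Nfkbiz, a regulator of NF-kB signalling in the list of IL-17 target genes, had -0.68. Fkbp5, a glucocorticoid-responsive chaperone, had -0.70, Gfap had -0.51 and Aif1 had 0.19. Over the alternatives fixed in advance Aif1 lay between 0.080 and 0.30. None of these 6 genes passed over all genes, and Gfap passed adjusted over the list of reactive astrocytes alone. Without CIE+IL17 Ab replicate 3 Nfkbiz passed with -1.07, and without CIE+IL17 Ab replicate 1 Gfap passed with -0.65. Gfap also passed in DESeq2, with the label number block and with the choroid plexus score. The sign of Il17ra turned without CIE+IgG replicate 2 (0.060) and CIE+IL17 Ab replicate 1 (0.043), and that of Il17rc without CIE+IgG replicate 2 (-0.069). Il17a, Lcn2, Il6, Tnf, Il1b and Ccl2 are absent from the deposited table and were not analysed here.

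The third comparison set the antibody group against the air controls, and it gave the highest count of the 3 comparisons. These groups differ in both ethanol exposure and the antibody, and the comparison cannot separate them. Nor can it separate them from the difference in thalamus and habenula genes. All 11 thalamus and habenula genes rose and 5 of 10 CA1 genes fell over all genes, and neither list passed with an estimated correlation (adjusted p = 0.384 and adjusted p = 0.662 with an estimated correlation). Shox2, a homeobox transcription factor of thalamic neurons, had 0 counts in the 3 Air+IgG libraries and 1203 in the CIE+IL17 Ab libraries, and it was at least 371-fold higher when set against a floor of 3 counts over the group. In CIE+IgG it had 87 counts, all in replicate 3. Tcf7l2 rose by 4.85 on the log2 scale from 6.19 ± 0.798 CPM, and Chrna3 rose by 4.81. Ccn3 fell from 116 ± 51.1 to 5.92 ± 4.34 CPM, and Rspo2 fell by 3.73 on the log2 scale.

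Between CIE+IL17 Ab and Air+IgG, 1990 genes passed, 1004 higher and 986 lower in CIE+IL17 Ab, and 737 differed by over 2 times. Among all tested genes, 35.3% had no overlap between both groups, where chance gives 10%. Of the 1990 genes, 1988 had none, which follows largely from their choice by p on the same libraries. The count was 0 without Air+IgG replicate 3, with 3912 genes at an unadjusted p under 0.05 in edgeR, so that no gene named here passed without that library. It was 478 and 335 without Air+IgG replicates 1 and 2, 169 without CIE+IL17 Ab replicate 2, and 1131 without CIE+IgG replicate 1. It was 1183 with only both groups in the fit and 1060 without the 2 libraries rich in Lars2. With the thalamus and habenula score as a term edgeR gave 0 genes, with 809 at an unadjusted p under 0.05, and with the striatum score 268. Within the libraries numbered 54 to 60 it was 2, which were Tcf7l2 and Slitrk6, the latter chosen after its values were seen.

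Of 41 lists, 11 passed in camera, 5 higher and 6 lower, and 0 passed with an estimated correlation. Fry gave 6, and camera gave 12 in the libraries numbered 54 to 60. All 11 thalamus and habenula genes rose, with a median of 2.92 (adjusted p = 3.29e-10, and adjusted p = 0.384 with an estimated correlation). In the CA1 list, 5 of 10 genes fell over all genes and 8 adjusted over the list alone, with a median of -1.42 (adjusted p = 3.57e-05, and adjusted p = 0.662 with an estimated correlation). The list of CA2 and CA3 pyramidal genes did not pass (adjusted p = 0.817), with a median of -0.323 and a mean of 0.0567. Of its 15 members, 5 rose and 4 fell over all genes, and 5 rose and 5 fell adjusted over the list alone. In the myelin list, 15 of 20 genes rose over all genes and 19 adjusted over the list alone, with a median of 0.71 (adjusted p = 3.11e-09, and adjusted p = 0.841 with an estimated correlation). Fa2h rose by 0.77 and the link protein Hapln2 by 1.01 on the log2 scale. Among immediate early genes 16 of 32 fell and 1 rose over all genes, and 19 fell and 2 rose adjusted over the list alone, with a median of -0.97 (adjusted p = 9.91e-08, and adjusted p = 0.662 with an estimated correlation). Fosl2 fell by 2.22 on the log2 scale, and Bdnf fell from 49.7 ± 17.8 to 18.5 ± 4.23 CPM. Dusp6, a phosphatase of MAP kinases, fell by 1.21 on the log2 scale.

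Genes of fatty acid synthesis and storage had a median of 0.40, with 5 higher and 1 lower over all genes, and 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.662 with an estimated correlation). The desaturase Scd1 rose from 185 ± 20.5 to 401 ± 124 CPM, and Srebf1, a transcription factor of lipid synthesis, rose by 0.65 on the log2 scale. Ependymal genes had a median of 1.36 and endothelial genes one of 0.25 (adjusted p = 0.00465 and 0.0325, and adjusted p = 0.841 with an estimated correlation). The glucose transporter Slc2a1 was the 1 endothelial gene that rose, by 0.50 on the log2 scale, and 0 ependymal genes passed. Without Air+IgG replicates 1 and 3 and CIE+IL17 Ab replicate 2 the endothelial list did not pass (0.108, 0.178 and 0.0934). Homeostatic microglia genes had a median of -0.26, with 3 of 18 lower over all genes and 5 adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.662 with an estimated correlation). Meningeal fibroblast genes had a median of -0.80, and 2 of 14 fell over all genes and adjusted over the list alone, Slc22a6 and Fmod, with log2 fold changes of -1.26 and -1.16 (adjusted p = 0.0182, and adjusted p = 0.841 with an estimated correlation). Without CIE+IL17 Ab replicate 1 this list did not pass (0.427), and its mean of -0.54 was -0.34. Dentate gyrus genes had a median of -0.61 and ribosomal protein genes one of -0.19 (adjusted p = 0.0155 and 0.0012, and adjusted p = 0.841 with an estimated correlation). In these lists 1 and 2 genes fell over all genes, among them Slc39a6 and Rplp1, and 0 adjusted over the list alone. The dentate gyrus list did not pass without Air+IgG replicate 2 (0.233) and CIE+IL17 Ab replicate 1 (0.131). The astrocyte list did not pass (adjusted p = 0.181), with a median of 0.23 and 15 of 17 members above 0, and the glutamate transporter Slc1a2 was its 1 member that fell, from 5768 ± 142 to 3670 ± 531 CPM. The mineralocorticoid receptor Nr3c2 fell by 1.53 on the log2 scale, in a list of the glucocorticoid response that did not pass (adjusted p = 0.856), with a median of 0.25 and a mean of -0.0054. Ptgs2, an enzyme of prostaglandin synthesis in the list of IL-17 target genes, fell by 2.22 on the log2 scale. That list, with 11 tested members, did not pass (adjusted p = 0.531). In it 1 gene fell over all genes and 2 adjusted over the list alone, the other being Nfkbiz with -0.88 (adjusted p = 0.0514 over all genes). Nfkbiz passed over all genes in DESeq2, in limma-voom, with the strict filter, with the choroid plexus score and without CIE+IL17 Ab replicate 3. Without CIE+IL17 Ab replicate 3 the log2 fold changes of Ptgs2 and Nfkbiz were -3.51 and -1.27. The mean of -0.85 of the dentate gyrus list was -0.46 without Air+IgG replicate 2 and -1.29 without CIE+IL17 Ab replicate 3.

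The antibody comparisons shared the CIE+IL17 Ab libraries. Of the 468 genes called against CIE+IgG, 457 were also called against Air+IgG, and all 457 had the same direction. Independent lists of these sizes would share 17.8 higher and 13.9 lower genes, and 100 simulations of unchanged groups gave a mean of 0.03 shared genes. The simulated value is chance with no effect, and it does not measure what the shared libraries add where effects are present. Part of the excess over the independent lists may come from the shared libraries.

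Whether the antibody moved expression back toward the air controls was examined by setting the antibody effect (CIE+IL17 Ab minus CIE+IgG) against the ethanol effect (CIE+IgG minus Air+IgG). No gene passed in both with opposite signs in edgeR's test and 1 did in DESeq2, Slc13a3, a dicarboxylate transporter, where edgeR gave 406 genes at an unadjusted p under 0.05 for the ethanol effect. Because edgeR called 0 genes for the ethanol effect, its count of genes changed back had to be 0 and does not answer the question. Simulations of unchanged groups, which hold no effect, gave a mean of 0.04 such genes. Among the 468 genes called with the antibody, 128 (27.4%) had the opposite sign in the ethanol effect. This share was not simulated for unchanged groups, and the genes were chosen by the antibody effect itself, so it is a description only. Across the 14696 genes, which are not independent replicates, the Pearson correlation of both effects was 0.135 and the Spearman correlation 0.204. Both effects share the CIE+IgG libraries, and 100 simulations of unchanged groups gave a mean Pearson correlation of -0.501 (SD 0.0222) and a mean Spearman correlation of -0.46. The covariance was 0.0254, against -0.0502 in the simulations, a difference of 0.0756. The simulations hold no effect, and an antibody effect unrelated to ethanol would by itself weaken a negative correlation. Their SD is also too narrow for these libraries. When the libraries were split into other groups, the Pearson correlation ran from -0.89 to 0.156. The differences from the simulations therefore do not show whether expression moved back. Without CIE+IgG replicate 3, whose striatum score was 2.42, the Pearson correlation was -0.15, and in the 6 libraries numbered 54 to 60 it was -0.079. It was 0.040 and 0.047 without CIE+IgG replicates 1 and 2, 0.057 without Air+IgG replicate 2, and 0.24 and 0.054 without CIE+IL17 Ab replicates 1 and 2. Over the 1000 genes with the smallest p for the ethanol effect it was -0.037, and over the genes called in any group 0.43. These subsets were chosen by the same data, and unchanged groups were not simulated for them.

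**Figure D3:**
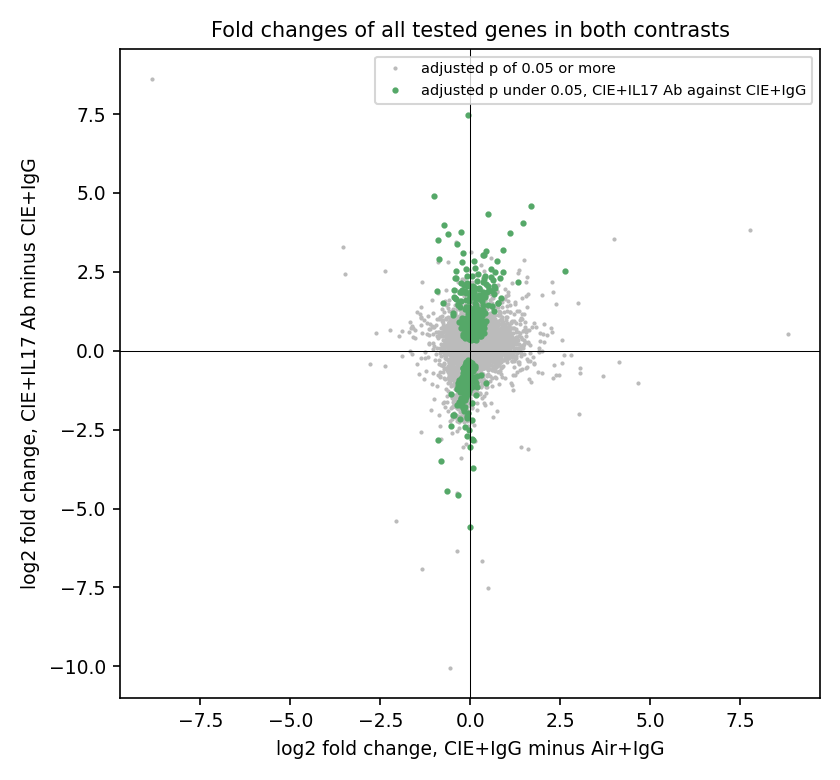
Log2 fold change of each tested gene for CIE+IgG minus Air+IgG (x axis) and for CIE+IL17 Ab minus CIE+IgG (y axis). Green points are the 468 genes with an adjusted p under 0.05 in the second contrast and grey points the others, and the Pearson correlation over all genes is 0.135.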

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

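Of the alternatives, the Lars2, score and label-number subsets below were chosen after the results were seen, and the others beforehand. Of 273 gene values, 272 kept direction and side of the threshold with DESeq2 size factors, which moved the median log2 fold change of all genes by less than 0.01. This was so for 273 with no filter, 271 with robust=FALSE and 217 of 222 with the strict filter. DESeq2 kept 231, with 36 newly passing and 6 lost, limma-voom kept 258, the fit of only both groups 199, and the label number block 259. DESeq2 gave 6 genes for CIE+IgG against Air+IgG, 1481 against CIE+IgG, 2192 in any group and 1 changed back. On simulated data its false calls were 39 of 165, 18 of 129 and 21 of 142 calls in the 3 comparisons. The fit of only both groups gave 1 and 1183 genes in the antibody comparisons, with fewer libraries for the spread. An adjusted p under 0.1 gave 1293, 3453 and 1918 in any group. The estimated correlation left 0, 0 and 0 lists, and the preset of 0.05 left 7 in CIE+IL17 Ab against CIE+IgG. The effect correlation was 0.204 by Spearman, 0.435 over genes called in any group and -0.0374 over 1000 genes. Ttr in CIE+IL17 Ab against Air+IgG was -0.68 in limma-voom. For these and the changes below the cause was not tested, unless the fit itself shows it.

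The replicate numbers share only a number: same-number pairs correlated from -0.27 to 0.249, 2 of 9 above 0.1, and 3 of 9 libraries correlated best with their own number. With the replicate block, 14 and 571 genes passed in the antibody comparisons, 16 in any group, and the effect correlation was 0.18. The label number block gave 776 genes against CIE+IgG and a correlation of 0.179.

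Without the 2 libraries rich in Lars2, 371 and 1060 genes passed in the antibody comparisons and 306 in any group, Fkbp5 and Bdnf had 0.15 and 0.096 in CIE+IgG against Air+IgG, Il17ra and Ttr 0.043 and 0.52 against CIE+IgG, and Aif1 0.015 against Air+IgG. Without Lars2 and AA474408 the correlation was 0.173. With the choroid plexus score, Bdnf and Ttr had 0.030 and -0.62 in CIE+IgG against Air+IgG, Il17ra 0.011 against CIE+IgG, Ttr -0.95 in CIE+IL17 Ab against Air+IgG, the correlation was 0.174 and 5 lists passed in CIE+IgG against Air+IgG. With the striatum score, 178, 268 and 145 genes passed, Bdnf had 0.0030 and the striatum list a mean of 0.12 in CIE+IgG against Air+IgG, and the correlation was 0.0967. In the libraries numbered 54 to 60, 1, 2 and 2 genes passed and the correlation was -0.0793.

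With the thalamus and habenula score in the fit, edgeR gave 0, 0 and 0 genes in the antibody comparisons and in any group, with 1017 and 809 at an unadjusted p under 0.05 in the antibody comparisons, and the correlation was -0.246. The score has a squared correlation of 0.957 with the antibody group, which leaves little to estimate the antibody term from, and 108 of 273 gene values changed sign. Lists are given below where the direction of camera's test turned. Means that kept their sign were those of thalamus and habenula genes (3.29 and 3.11 as reported). Against CIE+IgG, so did those of cholesterol synthesis (0.252) and neuropeptide genes (-0.399). The thalamus and habenula list was adjusted for its own score, so its values test nothing. In CIE+IL17 Ab against Air+IgG, the log2 fold changes were Abhd12b -3.84, Tspear -0.43, Adra2b -3.77, Akr1c18 4.12, Itprid1 2.75, Alox12b 2.39, Ly6g6e 0.27, Slc1a2 0.15, Fibcd1 0.79, Stard4 -0.38, Rorb -0.027, Slc39a6 0.45, Trpc6 0.71, Slco1a4 -0.44, Fam216b -2.54, Dynlrb2 -1.22, Aldh9a1 -0.41, Srebf1 -0.57, Nr3c2 0.73, Grin2d -0.57, Ptgs2 1.68, Cnr1 0.43, Lpl 0.56, Calb2 -0.71, Fa2h -0.32, Hapln2 -0.17, Abcc9 -0.41, Serpina3n 0.76, Six3 -0.40, Lef1 -0.25, Cacna1g -1.08, Gfap 0.82, Il17rc -0.0042, Bdnf 2.01, Ttr -6.19, and the list means were CA1 pyramidal 0.77, Cytosolic ribosome 0.15, Dentate gyrus granule cell 0.98, Endothelial -0.15, Ependymal -3.02, Fatty acid synthesis and storage -0.34, Oligodendrocyte and myelin -0.21, Thalamus and habenula 0.46. In CIE+IL17 Ab against CIE+IgG, the log2 fold changes were Tnnt1 -0.63, Wnt9b -0.99, Vipr2 -1.02, Akr1c18 4.21, Alox12b 2.21, Krt73 0.87, Lefty1 2.41, Spink8 1.2, Fibcd1 0.92, Stard4 -0.23, Rorb -0.058, Rplp0 0.034, Trpc6 1.07, C1ql2 4.10, Grin2d -0.92, Fa2h -0.66, Vtn -0.10, Serpina3n 0.53, Gfap 0.65, Cacna1g -1.21, Aif1 -0.56, Il17rc -0.37, Nfkbiz 0.061, Bdnf 2.10, and the list means were CA1 pyramidal 0.96, Cholesterol synthesis 0.0034, Cytosolic ribosome 0.17, Dentate gyrus granule cell 1.17, Endothelial -0.13, Fatty acid synthesis and storage -0.47, Neuropeptide and stress systems -0.23, Oligodendrocyte and myelin -0.53, Thalamus and habenula 0.44.

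Leaving out each library in turn, edgeR gave 0 to 0 genes in CIE+IgG against Air+IgG (208 to 758 at an unadjusted p under 0.05), 0 to 1314 against CIE+IgG, 0 to 2300 in CIE+IL17 Ab against Air+IgG, 21 to 1332 in any group and 0 to 0 changed back. The correlation ranged from -0.151 to 0.238, and the lists from 7 to 14, 10 to 15 and 10 to 13. In CIE+IgG against Air+IgG, Fkbp5 ranged from -0.22 to 0.15, Bdnf from -0.47 to 0.098 and the mean of the striatum list from -0.17 to 2.51, and against CIE+IgG, Il17ra ranged from -0.12 to 0.060, Il17rc from -0.069 to 0.25 and Ttr from -0.64 to 0.52. The cause was not tested. Depth, the number of libraries and their spread together limit the smaller changes, and depth was not varied alone. In simulated CIE+IL17 Ab against Air+IgG with 14696 genes, edgeR recovered 14.1% of genes changed by 1.5 times and 73.3% of those changed by 4 times.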

Other observations

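The tests of patterns here were chosen after the results were seen, and the counts of other splits were planned. Striatal genes were high in 2 libraries of different groups. Their score was 2.42 in CIE+IgG replicate 3 and 1.80 in CIE+IL17 Ab replicate 3, and at most 0.022 in the other 7. Choroid plexus genes were low in 2 others, with scores of -2.24 in Air+IgG replicate 2 and -3.51 in CIE+IL17 Ab replicate 1. Ttr had 3173 and 175 counts there and 22335 to 81905 elsewhere. The same libraries held 593544 and 495056 counts of Lars2, a mitochondrial leucyl-tRNA synthetase, which is 7.13% and 6.71% of their totals, against 301 to 2167 counts elsewhere. AA474408 had 1306 and 1040 counts there and 39 to 55 elsewhere. Lars2 shared 0 31-mers with 356 annotated rRNA transcripts, and no explanation was tested. Only transcripts annotated as rRNA in GENCODE M21 were searched, so rRNA sequence outside that annotation is not excluded.

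Thalamus and habenula genes were higher with the antibody, 11 of 11 in all 3 CIE+IL17 Ab libraries above all others, and CIE+IgG replicate 3, whose striatum score was 2.42, held 87 counts of Shox2 and 290 of Tcf7l2 against 0 and at most 59 in the other 5 libraries. The pattern did not rest on the 2 libraries rich in Lars2, since the median was 2.9 without them and 2.83 with them. Lars2 held 7.13% and 6.71% of their totals. That share is too small to move such a median far, so a few genes taking most counts was not tested by this. Tissue of the thalamus and habenula in these dissections is a candidate explanation: the 40 hippocampal neuron genes had a median of -0.589 (one-sided permutation p = 1e-05, the smallest 100000 permutations give). This p treats genes as independent, while the CA1, CA2 and CA3, and dentate gyrus lists had estimated correlations of 0.27, 0.39 and 0.608. None passed with them (adjusted p = 0.657, 0.906 and 0.906), so the support is limited. Nor did the lists fall evenly, with medians of -1.13, -0.496 and -0.325. Adjusted over the list alone, 4 CA2 and CA3 genes rose and 4 fell. An effect of the antibody on hippocampal cells cannot be told apart from such tissue, because the score has a squared correlation of 0.957 with the antibody group. The counts of 1 library without the antibody do not decide it.

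Of 32 immediate early genes, 23 were below 0 and 9 above 0 with the antibody, with a median of -0.87, and 6 fell over all genes. The list did not pass in camera with an estimated correlation (adjusted p = 0.83). Without the 2 libraries rich in Lars2 the median was -0.704. Their share of Lars2 is too small for this to test a few genes taking most counts. Dilution of hippocampal tissue may contribute and stays open: the median of -0.87 lay -0.28 from that of the hippocampal neuron genes (one-sided permutation p = 0.12 over genes taken as independent, 32 members). An effect of the antibody on these genes also stays open and was not tested.

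The meningeal fibroblast list did not pass in camera with an estimated correlation (adjusted p = 0.976). Of its 14 genes, 0 passed over all genes and 5 fell adjusted over the list alone. In CIE+IgG 11 of them had lower values than in Air+IgG, and 3 had higher values. Less meningeal tissue in these dissections may account for it, as the list varied as a unit within groups with an estimated correlation of 0.483. This is weak support, since 19 of 41 lists lay above 0.2. An effect of ethanol on meningeal cells cannot be told apart, since the exact two-sided permutation p of the score was 0.1, the smallest that 3 against 3 libraries allow.

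For each pair of groups the 6 libraries make 10 splits, too few for a share under 0.05. Counts as large as the real one came from 10 splits for genes and 6 for lists in CIE+IgG against Air+IgG (real 0 and 9, highest other 0 and 14). The 0 is edgeR's, with 406 genes at an unadjusted p under 0.05, 0 in limma-voom and 6 in DESeq2. For CIE+IL17 Ab against CIE+IgG they came from 1 and 5 (real 468 and 12, highest other 2 and 15), and for CIE+IL17 Ab against Air+IgG from 1 and 2 (real 1990 and 11, highest other 0 and 12). Of 100 splits of the 9 libraries, the real one included, 2 gave as many genes in any group (real 839, highest other 1194). The correlation of effects was as high in 2 (real 0.135, highest other 0.156). These shares are under 0.05, but they ask only whether the 9 labels are exchangeable. Both values changed when single libraries were left out, and the correlation turned negative without CIE+IgG replicate 3. Chance is not excluded for either. The splits with 1194, 711, 604 and 472 genes keep the 3 CIE+IL17 Ab libraries together. For genes changed back the real count is 0, so all 100 splits reach it by construction and nothing is tested. The highest other, 550, was on the split with 1194, where the CIE+IL17 Ab libraries stand in the place of CIE+IgG.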
